A study of Mus musculus with 6 samples.

How the data were processed

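RNA was measured in spinal cord tissue of wildtype C57BL/6 mice, 3 with a unilateral contusion of the cord at cervical level 5 and 3 with a laminectomy only, the removal of bone over the cord without a blow. Per the labels' protocols, total RNA was isolated with TRIzol and a Qiagen kit, and libraries were made with the Lexogen QuantSeq Forward kit, which primes on poly(A) and sequences near the 3′ end of transcripts. Per the labels' design text, 1 µg of total RNA per sample entered the libraries, and single-end reads of 50 bases were made on a HiSeq 4000. A count from such a library does not scale with transcript length, so no length correction was applied.

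The authors deposited 1 table of counts per sample, with whole-number read counts per Ensembl gene that are not normalized. Per the labels' design text, reads were aligned with STAR 2.7.2b to mouse genome mm10 with the Ensembl 96 annotation of GRCm38, and per the submitters' processing notes DESeq2 1.24.0 was among the tools. The tool that counted reads, its strand setting, its treatment of reads with several matches and any use of molecular identifiers are not given in the sources used here. Genes that share reads with near-identical copies, such as the haemoglobin genes, and overlapping or antisense genes are therefore uncertain. Each table held 43432 gene identifiers. A symbol was matched to 42462 of them, and identifiers without a symbol held 0.0884% of all counts. Positions came from GENCODE release M21, which is also on GRCm38 and held 42548 of the identifiers. No identifier number in the tables was above 104527, while 12988 of the 55536 genes in that release had higher numbers, so genes with newer identifiers were not analysed here.

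Total counts were 7591326, 11543633 and 3407176 in sham libraries 1 to 3 and 8229961, 6499952 and 5364263 in SCI libraries 1 to 3. A count of 3, taken as the limit that a count of 0 allows, corresponded to between 0.260 and 0.880 CPM, the count scaled to the library total. Reads without molecular identifiers are not independent molecules, so these limits and the intervals of count ratios cover counting error only. The series' design text gives 3 mice in each group, so libraries were treated as separate animals. Counts of 2 libraries of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 6.96 to 38.0 over genes with a summed count of at least 20, and no library was treated as a duplicate.

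The following choices were made before the data were examined. Genes passed edgeR's filterByExpr by group, which left 13560 of 21524 genes with at least 1 count. Libraries were scaled by TMM, and SCI was compared with sham by edgeR's quasi-likelihood F test with robust estimation (edgeR 4.0.16, R 4.3.3) in all 6 libraries without covariates. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are log2 values of SCI over sham with edgeR's prior count of 0.125. The standard error was the absolute log2 fold change divided by the square root of F. The common dispersion corresponded to a biological coefficient of variation of 19.9%. Group levels are means of TMM-scaled CPM with the standard deviation over 3 mice.

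Lists of genes for 22 responses and for cell types were fixed in advance. Of their 743 symbols, 4 had no match under the name listed and are not among the tested members. They were Cap23 (axon regeneration), Cyr61 and Ctgf (endothelial activation) and Lhfpl3 (oligodendrocyte precursors). With at least 5 tested members, 22 response lists and 16 cell type lists were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the 38 lists. Camera with an estimated correlation and fry were alternatives. The named genes were fixed by rule. They were the 8 genes at each end of the log2 fold changes among called genes with a mean CPM of at least 5, groups that did not overlap and no predicted gene name, the 3 members with the smallest p of each response list, and the 2 most abundant members of each cell type list. Haemoglobin and sex-linked genes were added as quality checks. Not every gene that the rule names is reported here. A gene named outside this rule is said to have been chosen after its values were seen. Composition of the libraries was compared by an exact two-sided permutation test of the group means, whose smallest possible p for 3 against 3 is 0.1.

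The procedure was tested on simulated data. Counts for the 13560 genes were drawn from the means, depths and trended dispersions of these libraries, with changed genes at 4 known sizes. A trended dispersion depends on abundance alone, and genes were drawn independently. Spread particular to a gene and variation shared between genes, such as the liver share, were therefore left out, and the rates may be too favourable. The SCI against sham comparison called 100% of genes lowered by 2 on the log2 scale, 59.2% of those lowered by 1, 66.0% of those raised by 1 and 96.0% of those raised by 2, each in the right direction. Of its calls, 4.29% were unchanged genes.

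Alternatives fixed in advance were DESeq2 size factors, upper-quartile factors and total counts in place of TMM, no filter, a filter of at least 5 CPM in 3 samples, the DESeq2 Wald test (DESeq2 1.42.0), limma voom, edgeR without robust estimation, the replicate number as a block, removal of mitochondrial, haemoglobin and ribosomal protein genes, and each library left out in turn. Transcripts of liver cells were then seen in every library. Marker lists for liver and other organs, a fit with the hepatocyte level per library as a covariate, and a fit without hepatocyte genes and Gm42418 were added after seeing the data. The hepatocyte level is the mean log2 CPM of 36 hepatocyte genes, of which 2 (Fgg and Hpx) also sit in a fixed list. Response and cell type lists can share members.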

Results

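The series asked how the transcriptome of the mouse spinal cord differs in the first hours after trauma. Spinal cord tissue was collected 4 h after a unilateral contusion at cervical level 5 with a force of 50 kdyn (SCI, n = 3 mice), delivered by the Infinite Horizon impactor, and from mice with a laminectomy only (sham, n = 3 mice). The collection time is stated for SCI, and that of the sham mice was not used here. The 6 libraries held between 3407176 counts (sham 3) and 11543633 counts (sham 2), and between 17535 and 18442 genes were detected in each.

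After contusion, transcripts of chemokines and of immediate early transcription factors were among those that rose. Ccl3, a chemokine that draws monocytes and neutrophils, went from 0.184 ± 0.160 CPM in sham to 24.8 ± 9.25 CPM in SCI (SD, n = 3 mice each). Its log2 fold change was 6.67 ± 0.47 (SE; edgeR quasi-likelihood test, adjusted p = 6.40e-06). In all, 120 genes were higher and 6 lower after injury among 13560 tested, and 108 and 5 of them by at least 2-fold. An unadjusted edgeR p under 0.05 was found for 1001 of the 13560 genes, where chance alone gives a share of 0.05. The groups did not overlap in 1853 genes, or 13.7% of those tested, where chance gives 10%. The counts depended on single libraries. Without sham 1 they were 62 higher and 1 lower. The sham libraries left in that fit, sham 2 and sham 3, differed most of all pairs within a group (chi-square per degree of freedom 38.0). A call lost there need not mean a changed fold change. For example, Rasgrp3 went from -1.20 ± 0.22 to -1.23 ± 0.27 (log2, SE) and Socs3 from 2.26 ± 0.45 to 2.01 ± 0.51. The lower genes numbered 12 without sham 2, 14 without sham 3, 3 without SCI 1, 3 without SCI 2 and 2 without SCI 3. With no filter on low counts 182 were higher and 42 lower, and with the hepatocyte level as a covariate, chosen after seeing the data, 217 were higher and 26 lower.

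Of 16 tested chemokines, 7 were higher and none was lower (8 higher when adjusted over the list alone). Cxcl2, a neutrophil chemokine at chromosome 5, 90903871 to 90905938 (GRCm38; ENSMUSG00000058427), had 1 count over the sham libraries and 329 over the SCI libraries, a ratio per total counts of 369 with a 95% counting interval of 65.8 to 14622. Ccl4 had 2 and 171 counts, a ratio of 95.9 (95% counting interval 26.1 to 798). Ccl4 lies at chromosome 11, 83662584 to 83664683 (ENSMUSG00000018930), beside Ccl3 at 83647844 to 83649355 on the same chromosome (ENSMUSG00000000982). Cxcl10, which attracts T cells and is induced by interferon, rose by 3.14 ± 0.44 on the log2 scale (SE, adjusted p = 0.00124). The chemokine list stood above the other genes by camera (adjusted p = 5.35e-27), and the call held with an estimated correlation (adjusted p = 0.0112).

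Immediate early genes, which are transcribed within minutes of a stimulus, were higher in 11 of 22 tested members (18 when adjusted over the list alone), and 21 of the 22 had a positive log2 fold change. Fosb, a subunit of the AP-1 transcription factor, rose by 4.63 ± 0.50 (log2, SE; adjusted p = 0.000141) from 0.767 ± 0.222 to 19.5 ± 12.3 CPM. Egr1, a zinc finger transcription factor, rose from 23.6 ± 7.41 to 110.3 ± 23.7 CPM, a log2 fold change of 2.25 ± 0.24. Ier3 and Maff rose by 2.30 ± 0.21 and 2.91 ± 0.27. The list's median log2 fold change was 1.34 (camera adjusted p = 9.67e-58, and adjusted p = 0.0116 with an estimated correlation). Among axon regeneration-associated genes, 2 of 18 were higher (4 adjusted over the list alone). They were Atf3, the injury-induced transcription factor at chromosome 1, 191170296 to 191218039 (ENSMUSG00000026628), which rose by 3.23 ± 0.32, and Klf6, which rose by 1.44 ± 0.20. That list was above the others at the preset correlation (adjusted p = 1.30e-07) and not with an estimated one (adjusted p = 0.0783 with an estimated correlation).

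**Figure D1:**
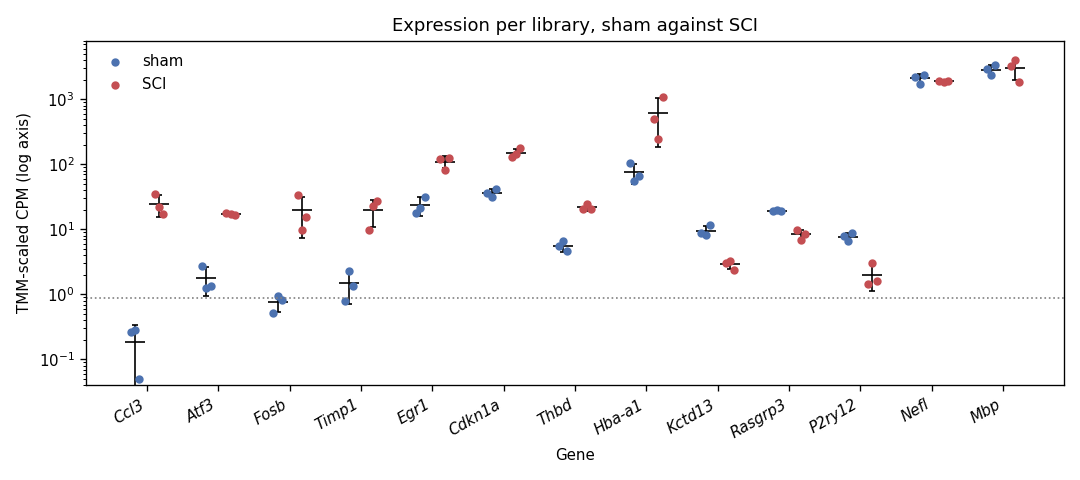
TMM-scaled CPM of 13 genes in each library on a log axis, with sham in blue and SCI in red; horizontal lines are group means, bars are 1 SD over 3 mice, the dotted line is 3 counts in the shallowest library, and a library with no count is drawn near the lower end. Ccl3 lies between 17.05 and 35.1 CPM in SCI and at or under 0.289 CPM in sham, while the neuronal Nefl and the myelin gene Mbp overlap between groups; P2ry12 was chosen after its values were seen.

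Genes of coagulation and matrix remodelling were higher in 8 of 19 tested members (13 adjusted over the list alone). Their median log2 fold change was 1.36 (camera adjusted p = 1.59e-30, and adjusted p = 0.0116 with an estimated correlation). Adamts1, a secreted metalloproteinase, rose from 14.1 ± 3.58 to 64.9 ± 8.04 CPM (log2 fold change 2.18 ± 0.21, adjusted p = 6.37e-05). Timp1, an inhibitor of metalloproteinases that also sits in the reactive astrocyte and STAT3 lists, rose by 3.63 ± 0.43, and Thbd, the thrombomodulin of endothelial cells, by 1.93 ± 0.24. Endothelial activation genes were higher in 4 of 15 members (7 adjusted over the list alone). Camera's adjusted p for them was 9.73e-14, and 0.0116 with an estimated correlation. Esm1, a proteoglycan secreted by activated endothelium, rose by 3.29 ± 0.49, and Adamts9 by 2.41 ± 0.31. Markers of resting endothelium did not stand apart as a list (adjusted p = 0.954), and the transporters Slco1a4 and Mfsd2a had log2 fold changes of -0.07 ± 0.22 and -0.04 ± 0.23.

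Reactive astrocyte genes were higher in 7 of 20 tested members (11 adjusted over the list alone). Their median log2 fold change was 1.06 (camera adjusted p = 4.41e-25, and adjusted p = 0.0167 with an estimated correlation). Sphk1, a sphingosine kinase, rose by 2.67 ± 0.40. Gfap, the intermediate filament of astrocytes, chosen after its values were seen, was at 288 ± 27.3 CPM in sham and 371 ± 18.0 CPM in SCI, a log2 fold change of 0.37 ± 0.20 that did not pass the test (adjusted p = 0.740). Markers of the astrocyte as a cell type did not stand apart (adjusted p = 0.212).

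Glucocorticoid-responsive genes were higher in 6 of 19 members (10 adjusted over the list alone). Camera's adjusted p for them was 8.11e-24, and 0.0154 with an estimated correlation. Sgk1, a kinase of ion transport, rose from 43.0 ± 3.17 to 129 ± 21.8 CPM (log2 fold change 1.59 ± 0.19), and Map3k6 rose by 2.95 ± 0.35. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 36.8 ± 5.002 to 152 ± 22.9 CPM, a log2 fold change of 2.05 ± 0.20 (adjusted p = 5.74e-05). It is also the called member among the 18 tested p53 target genes (3 members higher when adjusted over the list alone). The p53 list was above the others (camera adjusted p = 1.83e-06, and adjusted p = 0.0360 with an estimated correlation). Of 18 NF-kB target genes, 2 were higher (12 adjusted over the list alone). Camera's adjusted p for the NF-kB list was 5.16e-16, and 0.0154 with an estimated correlation. Ptgs2, the inducible cyclooxygenase, had no count in the sham libraries and 4.90 ± 1.32 CPM in SCI, at least 37.4-fold higher against a floor of 3 counts over the sham group. The list's median log2 fold change was 0.86.

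Several lists were above the other genes at the preset correlation alone. Cytokines had 2 of 9 members higher (5 adjusted over the list alone; adjusted p = 3.48e-07, and adjusted p = 0.0802 with an estimated correlation), among them the interleukin-1 receptor antagonist Il1rn, which rose by 1.75 ± 0.29. STAT3 and acute-phase genes had 2 of 22 members higher (3 adjusted over the list alone; adjusted p = 6.18e-06, and adjusted p = 0.264 with an estimated correlation), and many of them are abundant in liver, whose transcripts were present in every library. Socs3, a feedback inhibitor of STAT3 signalling, rose by 2.26 ± 0.45 (adjusted p = 0.0208). That call was lost without sham 1 (adjusted p = 0.155), SCI 1 (0.0646) or SCI 2 (0.162), and with limma voom (0.0733). Interferon-stimulated genes had 2 of 25 members higher (2 adjusted over the list alone; adjusted p = 2.82e-05, and adjusted p = 0.3003 with an estimated correlation). These were Gbp2 and Rsad2. Neither was called without sham 1 (adjusted p = 0.0869 and 0.130), Gbp2 was not without SCI 2 (0.0716), and Rsad2 was not without SCI 3 (0.117), with limma voom (0.0921) or with the replicate number as a block (0.141). Of 22 cholesterol synthesis genes, none was called over all genes, 6 were higher when adjusted over the list alone and 20 had a positive log2 fold change (adjusted p = 1.66e-10, and adjusted p = 0.0616 with an estimated correlation). Mvd, a mevalonate pathway enzyme, was at 12.5 ± 1.80 CPM in sham and 23.2 ± 2.35 CPM in SCI (adjusted p = 0.0769), and passed without a filter (adjusted p = 0.0244) or with the DESeq2 Wald test (0.0372).

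**Figure D2:**
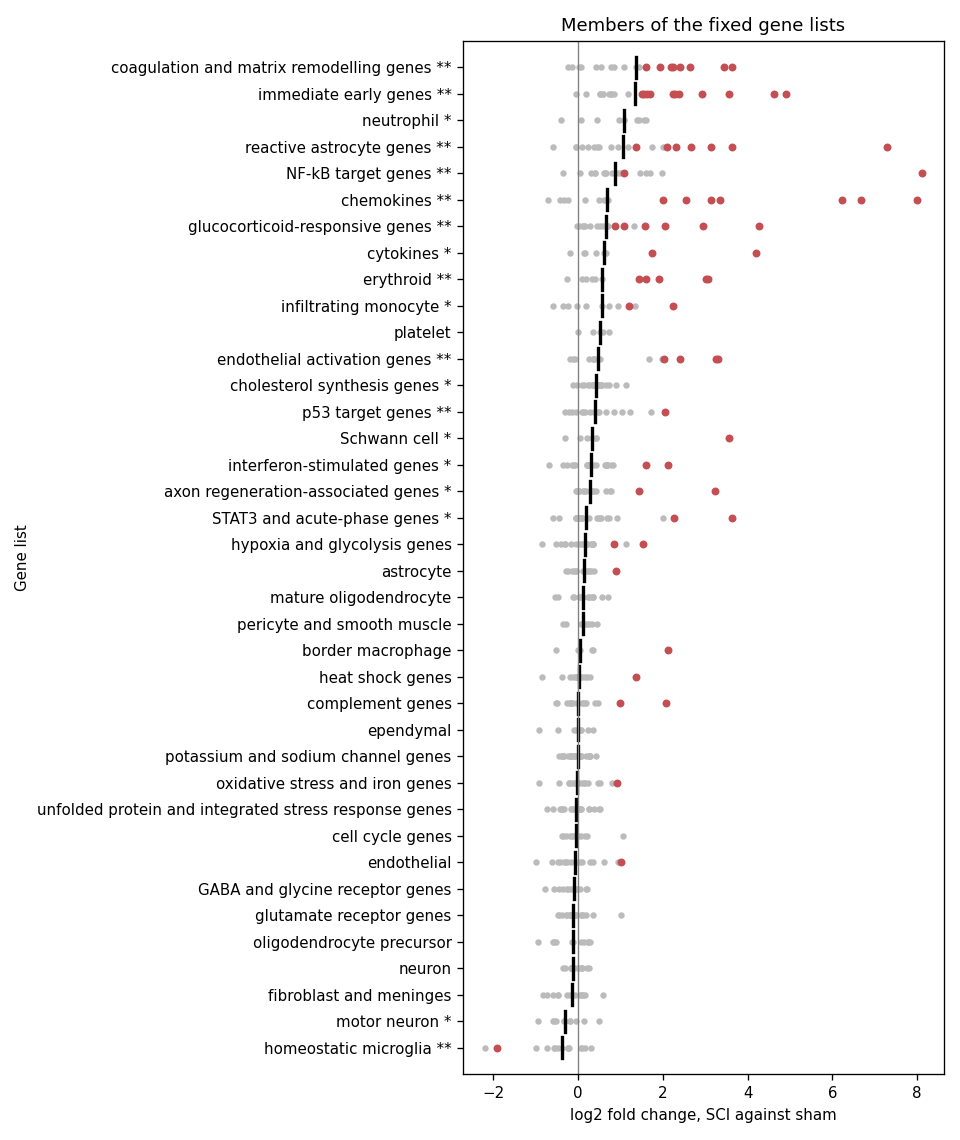
Log2 fold change of SCI against sham for each tested member of the 38 lists, with called members in red, others in grey and the list median as a black line; 1 asterisk marks a camera call at the preset correlation and 2 a call that also held with an estimated correlation. The highest medians belong to coagulation and matrix genes (1.36) and immediate early genes (1.34), and the lowest to homeostatic microglia (-0.38); fitted values of the 2 members without sham counts depend on the prior count.

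Among cell type lists, erythroid markers were higher in 5 of 11 tested members (5 adjusted over the list alone; camera adjusted p = 1.07e-14, and adjusted p = 0.0483 with an estimated correlation), a call that was lost with fry (adjusted p = 0.05998). Hba-a1, an alpha globin at chromosome 11, 32283511 to 32284465, went from 75.3 ± 25.2 to 613 ± 427 CPM (log2 fold change 3.02 ± 0.42, adjusted p = 0.00124), and its near-identical copy Hba-a2 rose by 3.07 ± 0.42, so reads between them are uncertain. The calls of both were lost without sham 2 (adjusted p = 0.458 and 0.445) or sham 3 (0.313 and 0.307), and with the hepatocyte level as a covariate, where the log2 fold changes were 3.01 ± 0.80 and 3.07 ± 0.81 (SE; adjusted p = 0.344 and 0.341). There the fold changes stayed and the standard errors grew. The beta globin Hbb-bt rose from 83.5 ± 10.3 to 312 ± 123 CPM (log2 fold change 1.90 ± 0.27, edgeR adjusted p = 0.00135). Its call held without each single library and was lost with the hepatocyte level as a covariate (1.90 ± 0.34, adjusted p = 0.109). Hbb-bs rose by 1.60 ± 0.29 (edgeR adjusted p = 0.01035) and lost its call without sham 1, SCI 1 or SCI 3 and with the replicate number as a block. Haemoglobin genes held 0.0722 ± 0.0095% of counts in sham and 0.288 ± 0.116% in SCI, higher in each SCI library than in any sham library (exact permutation test, p = 0.1, the smallest 3 against 3 can give; adjusted p = 0.35 over 7 measures). Neutrophil markers had no member called over all genes and 6 of 10 higher when adjusted over the list alone (camera adjusted p = 6.14e-08, and adjusted p = 0.0604 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, was at 12.5 ± 7.85 CPM in sham and 27.6 ± 3.59 CPM in SCI (adjusted p = 0.241), and passed without sham 2 (adjusted p = 0.000551), with no filter on low counts (0.000786) or with the hepatocyte level as a covariate (0.000324). Infiltrating monocyte markers had 2 of 11 members higher (3 adjusted over the list alone; adjusted p = 0.00186, and adjusted p = 0.180 with an estimated correlation). Those were Thbs1, a matrix protein also listed with coagulation, and Emilin2, while the abundant Lyz2 had a log2 fold change of -0.03 ± 0.20. Thbs1 and Emilin2 were chosen after their values were seen. They lost their calls without sham 1 (adjusted p = 0.0763 and 0.1248) or SCI 3 (0.0817 and 0.0996), Thbs1 without SCI 1 (0.0516) and Emilin2 without SCI 2 (0.103).

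Markers of homeostatic microglia, the resting macrophages of the cord, were lower as a list (median log2 fold change -0.38, camera adjusted p = 3.33e-05, and adjusted p = 0.0473 with an estimated correlation). Of 15 tested members, 1 was lower over all genes and 4 when adjusted over the list alone. The called member, P2ry12, a purinergic receptor at chromosome 3, 59216272 to 59262871 (ENSMUSG00000036353), was chosen after its values were seen. It was at 7.74 ± 1.09 CPM in sham and 2.02 ± 0.876 CPM in SCI (log2 fold change -1.91 ± 0.37, adjusted p = 0.0157). Its call was lost without sham 1 (adjusted p = 0.0940), SCI 1 (0.119) or SCI 3 (0.0758), and with the replicate number as a block (0.0948). The most abundant members, Sparc and Csf1r, had log2 fold changes of 0.17 ± 0.23 and 0.10 ± 0.21. Motor neuron markers were lower as a list at the preset correlation (adjusted p = 0.0249, and adjusted p = 0.180 with an estimated correlation) with no member called over all genes or over the list alone. That list call was lost without sham 1 (adjusted p = 0.0792) or SCI 1 (0.144). Chat and Slc5a7, both of acetylcholine synthesis, had log2 fold changes of -0.34 ± 0.23 and -0.58 ± 0.18. The Schwann cell list was above the others (adjusted p = 0.00746, and adjusted p = 0.101 with an estimated correlation) with 1 of 7 members higher (1 adjusted over the list alone), the immediate early gene Egr2 (chosen after its values were seen), and lost its call without sham 3 (adjusted p = 0.0920) or when genes in more than 1 list were left out (0.285). Pmp22, a myelin gene of that list, had a log2 fold change of 0.42 ± 0.19 (adjusted p = 0.631).

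The named genes lower after injury were Kctd13, an adaptor of a ubiquitin ligase, Rasgrp3, an activator of Ras, Trim59 and the transcription factor Zic1. Rasgrp3, at chromosome 17, 75435896 to 75529054 (ENSMUSG00000071042), fell from 19.4 ± 0.521 to 8.42 ± 1.43 CPM (log2 fold change -1.20 ± 0.22, adjusted p = 0.0117). Kctd13 fell from 9.53 ± 1.85 to 2.91 ± 0.481 CPM, a log2 fold change of -1.67 ± 0.31 (adjusted p = 0.0114). Both calls were lost without sham 1 (adjusted p = 0.0663 and 0.0544), that of Rasgrp3 also without SCI 2 (0.110) and that of Kctd13 without SCI 1 (0.0646) or SCI 3 (0.0567). With the replicate number as a block neither Rasgrp3 nor Kctd13 was called (adjusted p = 0.0734 and 0.0790). Trim59 (log2 fold change -1.90 ± 0.41) lost its call without sham 1, sham 3, SCI 2 or SCI 3, with an adjusted p of 0.0555, 0.0573, 0.202 and 0.187. Zic1 (-0.98 ± 0.22) lost it without sham 1, sham 3, SCI 1, SCI 2 or SCI 3, with an adjusted p of 0.155, 0.109, 0.267, 0.0731 and 0.211. Trim59 and Zic1 were also not called with total counts (adjusted p = 0.0507 and 0.150) or the stricter filter (0.0661 and 0.0618). The same held with limma voom (adjusted p = 0.0545 and 0.0605) and with the replicate number as a block (0.164 and 0.244). The other 2 lower genes were P2ry12 and Ranbp3l. Ranbp3l, chosen after its values were seen, fell from 5.46 ± 1.00 to 0.647 ± 0.292 CPM (log2 fold change -2.99 ± 0.45, adjusted p = 0.00243), and its call held without each single library.

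The remaining lists did not stand apart from the other genes with all libraries and the filter on low counts. With no filter, complement genes were higher (adjusted p = 0.0176) and GABA and glycine receptor genes lower (0.0475). Neurons had 0 of 18 markers called over all genes or over the list alone by edgeR (camera adjusted p = 0.375), and the neurofilament genes Nefl and Nefm each had a log2 fold change of -0.14 ± 0.25. Without sham 2, the library with the most liver transcripts, the neuron list was lower (adjusted p = 0.00108), as were those of glutamate receptors (0.000424), GABA and glycine receptors (0.000208), potassium and sodium channels (0.000669) and oligodendrocyte precursors (0.00509), while complement (3.49e-06), border macrophage (0.00509) and oxidative stress genes (0.0386) were higher. These calls without a library are at the preset correlation. In all libraries, the estimated correlation between members of the neuron, receptor, channel, oligodendrocyte precursor and complement lists was 0.418 to 0.669, and their adjusted p with an estimated correlation was 0.756 to 0.862. At the preset correlation with all libraries these 8 lists had an adjusted p of 0.375, 0.470, 0.0894, 0.526, 0.365, 0.0894, 0.0892 and 0.365. Within the complement list the receptor gene C3ar1 rose by 2.06 ± 0.29, 1 of 2 called among 17 members (2 adjusted over the list alone). Resting endothelium had 1 of 17 members higher (2 adjusted over the list alone), and hypoxia and glycolysis genes 2 of 23 (3 adjusted over the list alone). The latter were Pfkfb3 and Hk2. Neither was called without sham 1 (adjusted p = 0.197 and 0.262), sham 2 (0.0616 and 0.108) or SCI 1 (0.197 and 0.258), nor with upper-quartile factors (0.0501 and 0.0521), total counts (0.0927 and 0.0555) or the block (0.198 and 0.121). Pfkfb3 also lost its call without SCI 2 (0.236), and Hk2 without SCI 3 (0.178), with the stricter filter (0.0586) or with limma voom (0.0502). Astrocyte markers (15), border macrophage markers (7), heat shock genes (18) and oxidative stress genes (19) each had 1 member higher, over all genes and adjusted over the list alone. These were Sox9, Pf4 (both chosen after their values were seen), Hspb1 and Srxn1. None of the 4 was called without sham 1 (adjusted p = 0.175, 0.0540, 0.0589 and 0.130). Sox9 and Srxn1 were also not called without SCI 1 (0.181 and 0.0770), without SCI 2 (0.147 and 0.202) or with the block (0.164 and 0.178), nor Sox9 with total counts (0.0563). The other lists of this group had none called over all genes. Adjusted over the list alone, 1 mature oligodendrocyte marker was higher and 1 ependymal marker lower. Mature oligodendrocyte (0.340), pericyte and smooth muscle (0.656), fibroblast and meninges (0.223), ependymal (0.338) and platelet markers (0.134) did not pass at these adjusted p-values, nor did hypoxia and glycolysis (0.0892), unfolded protein and integrated stress response (0.672), heat shock (0.503) and cell cycle genes (0.725). Of these, heat shock (adjusted p = 0.0148) and fibroblast and meninges (0.0184) passed without sham 3, as did astrocyte markers (0.0348). Mature oligodendrocyte markers (0.0229) and hypoxia genes (0.0262) passed without SCI 3. Platelet markers passed without sham 1 (0.0275) or SCI 1 (0.0349), complement genes without SCI 2 (0.0106), and GABA and glycine receptors without SCI 1 (0.0289). Median and test differed in sign for oxidative stress genes (median -0.02, mean 0.06, higher), resting endothelium (median -0.07, mean -0.02, higher) and ependymal markers (median 0.00, mean -0.10, lower). Lymphocyte, skeletal muscle and dorsal root ganglion neuron lists had 3, 4 and 3 tested members and were not tested as lists, and none of their members was called.

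Transcripts of liver cells were abundant in all 6 libraries. Alb, the serum albumin of hepatocytes, was between 26179 and 57166 CPM of total counts. A set of 36 hepatocyte genes together held 9.26, 12.98 and 6.92% of counts in sham 1 to 3 and 9.002, 8.77 and 9.06% in SCI 1 to 3. Their share did not separate the groups (exact permutation test, p = 0.7; adjusted p = 0.933), none of the 36 was called by edgeR, and their median log2 fold change was -0.02. Xist, expressed from the inactive X chromosome of females, was at 215 ± 73.2 CPM in sham and 217 ± 35.8 CPM in SCI, and the Y-linked Ddx3y at 45.8 ± 7.78 and 53.2 ± 2.39 CPM, so both kinds of transcript were present in each library. Ribosomal protein genes held 1.107 ± 0.0263% of counts in sham and 1.186 ± 0.0643% in SCI, higher in each SCI library than in any sham library. The exact permutation test gave p = 0.1, the smallest possible, and an adjusted p of 0.35. Mitochondrially encoded genes held 15.2 ± 0.447% of counts in sham and 14.1 ± 0.600% in SCI (exact permutation test, p = 0.2), and Gm42418, which overlaps a ribosomal RNA repeat, 10.8 ± 1.11% and 10.6 ± 1.80% (exact p = 1).

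**Figure D3:**
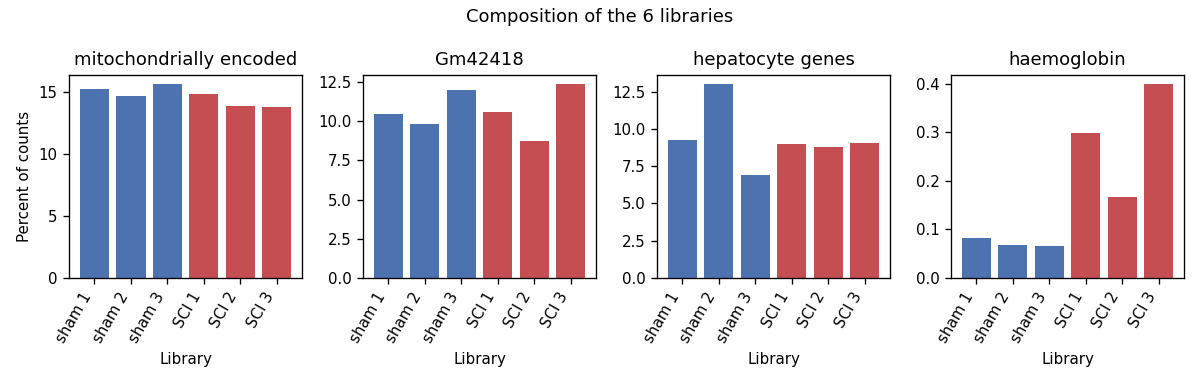
Percent of counts in mitochondrially encoded genes, Gm42418, 36 hepatocyte genes and haemoglobin genes in each library, with sham in blue and SCI in red and each axis starting at 0. Haemoglobin is higher in the 3 SCI libraries than in the 3 sham libraries, and hepatocyte genes range from 6.92% (sham 3) to 12.98% (sham 2).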

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

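No named gene, list or count changed direction among called results under any alternative that was run. Genes higher after injury numbered between 92 and 141 under the planned scalings, filters and tests except without a filter (182, and 42 lower over 21524 genes) and under the block, and 217 with the hepatocyte level as a covariate, an alternative chosen after seeing the data (26 lower, with 117 of the 120 and all 6 shared). Genes lower numbered 3 under the stricter filter, with fewer genes tested, and 11 with the DESeq2 Wald test; the cause of the latter was not tested. Leaving out 1 library at a time gave 62 (without sham 1) to 132 higher genes (without sham 3), 1 to 14 lower genes and 19 to 27 called lists, with fewer samples in each fit. Of 42 called genes named by rule, 24 were called in all 6 of these fits and 15 lost their call without sham 1. Lists called numbered 10 with an estimated correlation, 12 by fry and 19 as reported. Against TMM, the median of all genes moved by -0.04 (log2) with upper-quartile factors and 0.02 with total counts. Same-numbered libraries deviated from their group means with correlations of -0.08, -0.07 and -0.17, and no sample correlated best with its own number across groups. These values gave no sign that the numbers pair the samples, but groups of 3 cannot exclude a shared batch. With the replicate number as a block, 81 genes were higher and 1 lower. In simulated data of this depth, without variation shared between genes, 59.2% of genes lowered by 1 on the log2 scale were called. This limits what the depth and 3 mice per group can show, and the real share may be lower.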

Other observations

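The genes of this paragraph lie in none of the fixed lists and were chosen after their values were seen; 63 of the 126 called genes were in no list, 58 higher and 5 lower. Flnc, an actin crosslinker, rose from 1.59 ± 0.332 to 12.5 ± 0.490 CPM (SD, n = 3 mice each; log2 fold change 2.94 ± 0.31, edgeR adjusted p = 0.000109). Ezr, which ties actin to the membrane, rose by 1.48 ± 0.22, the small GTPase Rhoj by 1.96 ± 0.26, and Pdpn, a surface glycoprotein of meninges and reactive glia, by 2.17 ± 0.27 from 9.40 ± 1.14 CPM. Ptges, the prostaglandin E synthase that acts after the product of Ptgs2, rose by 3.85 ± 0.60, and the transcription factor Cebpd by 2.38 ± 0.22 from 7.62 ± 1.22 to 40.4 ± 7.11 CPM. Gpr84, a receptor of activated myeloid cells, had 3 counts over the sham libraries and 97 over the SCI libraries, a ratio of 36.3 with a 95% counting interval of 12.05 to 179. The calls of these genes held without each single library.

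All tests of the 3 patterns below were chosen after the pattern was seen, and those on slope, Kupffer and sinusoidal genes, neutrophil ratio and microglial markers also after the values they measure. The tests on Clec4f and Stab2 and on the neutrophil ratio replaced earlier ones after the outcomes of those were known. The first of the earlier ones was a correlation of Xist with the hepatocyte level (r = 0.89, exact permutation p = 0.0431, Benjamini-Hochberg adjusted p = 0.0646 over 6 measures). Its Spearman's rho was 0.94 (exact permutation p = 0.0167, adjusted p = 0.0333). It was dropped because r fell to 0.44 without sham 2 and sham 3, although the r of the Kupffer and sinusoidal genes, kept below, fell further, to 0.28. The second was the rise of S100a8 and S100a9 over the sham mean (17.7 to 34.1 CPM in SCI libraries) against that of Ccl3, Ccl4 and Cxcl2 (41.6 to 63.4 CPM), which does not bear on how many transcripts each neutrophil holds. Nothing is drawn here from either. The 2 tests on microglial markers also replaced earlier ones after their outcomes were known. Those were Cochran's Q over 10 markers picked after their values were seen (30.3, 95% reference value 16.9), and over 8 of them, and the value of P2ry12 alone under the covariate, which had argued against dilution. The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05; the real split gave 126 called genes, the highest of the others 0, and 1 split of the 10 reached the real value.

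Hepatocyte transcripts were found in all 6 spinal cord libraries, with female-biased liver genes at 350 to 653 CPM in sum and male-biased ones at 0.746 to 3.64 CPM, while kidney, pancreas, heart, testis and fat markers stayed under 1 CPM in sum, lung markers under 3 CPM and skin markers under 5 CPM. An equal number of liver reads added to every library is argued against by the slope of log2 hepatocyte counts on log2 other counts, 1.51 (SE 0.12), and 1.03 (SE 0.09) without sham 2 and sham 3. Hepatocyte genes switched on in the cord's own cells are argued against by Clec4f and Stab2, genes of Kupffer cells and liver sinusoids, whose lowest level in any library was 26.9 CPM against a floor of at most 0.880 CPM. Hepatocyte, Kupffer and sinusoidal genes thus lay above that floor in every library, while the step at which liver transcripts entered stays open. On liver tissue or RNA mixed into every sample, the correlation between these genes cannot decide. Kupffer and sinusoidal genes followed the hepatocyte level with Pearson's r = 0.82 (exact permutation p = 0.0889, adjusted p = 0.107; Spearman's rho 0.77, p = 0.103). That r rests on sham 2 and sham 3, without which it was 0.28. Without sham 2 and sham 3 the hepatocyte share spanned only 8.77 to 9.26% of counts, so that lower r cannot decide the question. Y-linked genes went the other way (r = -0.94, exact permutation p = 0.00139, adjusted p = 0.00833; rho = -1, p = 0.00278; r = -0.95 without those libraries), so the liver transcripts may come from female tissue and the cord from male mice, and mixing of tissue, RNA or libraries cannot be told apart here.

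Chemokine transcripts were higher after injury. A rise that only followed the amount of liver RNA is argued against by the share of hepatocyte genes, which did not separate the groups. It was 9.72 ± 3.06% of counts in sham and 8.94 ± 0.151% in SCI (SD). With the hepatocyte level as a covariate, Ccl3 had a log2 fold change of 6.62 (SE 0.45), and all 7 called chemokines stayed called. A covariate with similar group means could hardly move a group difference. Whether the liver RNA itself held more chemokine transcripts in SCI cannot be told from this fit. More blood neutrophils with unchanged expression stay open. The ratio of Ccl3, Ccl4 and Cxcl2 to S100a8 and S100a9 was at least 0.734 in SCI libraries and at most 0.0265 in sham libraries. In sham 1 to 3, however, S100a8 and S100a9 summed to 19.8, 37.2 and 11.7 CPM. That is the order of the hepatocyte share in these libraries (9.26, 12.98 and 6.92%), an order that 3 libraries can share by chance. SCI 1 to 3 did not follow it, with 40.6, 57.0 and 55.3 CPM at shares of 9.002, 8.77 and 9.06%, which differ little. The sham level of S100a8 and S100a9 may still be partly of liver origin, which was not tested, so the sham ratio is no clear baseline for neutrophils of the cord. Which cells hold the transcripts was not tested.

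Markers of homeostatic microglia were lower after injury, with P2ry12 the 1 marker called over all genes and several others at low counts. Dilution by liver RNA would need more of it in SCI, which is argued against by the share of hepatocyte genes. That share was 9.72 ± 3.06% of counts in sham and 8.94 ± 0.151% in SCI (SD), with a median log2 fold change of -0.02. Without sham 3, the only sham library with a smaller share than the SCI libraries, the list was still called lower at the preset correlation. With the hepatocyte level as a covariate the list's median log2 fold change was -0.33, and P2ry12 was at -1.93 (SE 0.36). Camera's adjusted p in that fit was 0.000116 at the preset correlation and 0.140 with an estimated one, so the fit alone cannot decide. A lower share of microglial RNA stays open. Cochran's Q was 46.6 over the 15 tested members (95% reference value 23.7), 21.7 (21.03) without P2ry12, the pattern's top gene, and Gpr34, near the floor in SCI at 0.411 CPM, and 11.86 (18.3) also without Sparc and Csf1r, which other cells express too. The weighted mean log2 fold change of those 11 was -0.42 (SE 0.09), so a common fall and a change in single genes cannot be told apart, and whether transcription changed within microglia was not tested.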
